A study of Mus musculus with 12 samples.

How the data were processed

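RNA from Ly6C-high blood monocytes from 6 TRIM33 and 6 WT samples of mice was measured on single-colour expression arrays. Per the labels' protocols, total RNA was extracted with an RNeasy Mini kit and 900 pg of it was amplified and biotinylated with the NuGEN Ovation Pico V2 protocol. The labels' treatment text describes a sort of CD4 T cells, while the source names and the series design give monocytes sorted for CD11b, CD115 and high Ly6C; the latter was followed.

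The deposited values are log2 expression values, 1 per gene-level feature, made by the authors. Per the submitters' processing notes, RMA and Partek were used, with versions not given in the sources used here. The chip definition, the genome build and any batch step are not given in the sources used here either. RMA adjusts background, equalises the distribution of values between arrays and summarises probes. It can hide a shift shared by most genes, and differences between dim genes come out compressed. Amplification from picogram amounts adds spread between arrays. Arrays carry no counting depth, so precision is set by the number of arrays and the signal over background.

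The table holds 24479 features on 12 arrays. Of these, 23281 carried 1 gene symbol, 0 several and 1198 none; features without a symbol are unnamed here and were tested only as an alternative, in which 0 of them passed. Symbols were looked up by Entrez number in a RefSeq gene table of assembly GRCm38.p6, which changed 0 of them. That table was used only for names and for which genes neighbour each other. For the 2 symbols with more than 1 feature the feature of the higher mean was kept, which left 23279 genes. Of the 456 genes on the fixed lists, 30 are not analysed here, Lyz2 among them.

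Groups were taken from the genotype labels. Genes were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3 on the log2 values, with genotype only, all 12 arrays and a Benjamini-Hochberg adjusted p threshold of 0.05. Gene lists were tested with camera (inter-gene correlation 0.01) where 3 or more genes were measured, adjusted over the 27 lists. Camera with an estimated correlation and fry were run beside it. Exact two-sided permutation tests covered Trim33, Lyz1 and the list means. No pseudocount was needed. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

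Named genes followed a rule: Trim33, its paralogs and Lyz2; the 12 largest rises and falls past the threshold or, where fewer than 5 passed in a direction, the 10 with the smallest p; and up to 4 members of each list past the threshold, or the 2 with the smallest p. Predicted genes without a name were counted and not named under the second part; A930005H10Rik, Emp1, Stfa3, Yeats4, Frrs1, Oas2, Isg15, Ifnb1, Eif2s3y and the genes added by the array set were named after their values were seen. The lists covered Trim33 and its paralogs, Ly6C-high and Ly6C-low monocytes, macrophage differentiation, MHC class II and dendritic cells, the type I interferon response, cytokines and chemokines, TGF-beta and SMAD, adhesion, phagocytosis, myeloid transcription factors, cell cycle, handling stress, DNA damage, ribosomal proteins, the respiratory chain, neutrophils, B, T and natural killer cells, erythroid cells, platelets, eosinophils and basophils, progenitors, plasmacytoid dendritic cells, sex-linked genes and the neighbours of Trim33. Groups, tests, lists and the rule were fixed before the data were examined, apart from the exact tests of Lyz1, of the list means and within the array sets.

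The 2 array sets were found by average-linkage clustering of 1 minus Pearson's r over all features, without use of genotype. Fits with the set as a block, within each set (3 arrays against 3), with an interaction of genotype and set, and with an interaction of genotype and preparation beside the set were added after the data were seen. Other choices tried were another normalization, filters on dim features, other variance models, array weights, other thresholds, preparation as a covariate, the mix number as a replicate block, the mixes or the other arrays alone, and each array left out in turn.

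The gene test was tested on simulated values for 23279 genes with 200 changed. Without a block it recovered 40% of genes changed by 0.5 on the log2 scale, 82% at 1, 98% at 2 and 100% at 3, with 2 false calls. With the array set as a block it recovered 60%, 94%, 100% and 100%, with 8 false calls. A simulated list of 28 genes shifted by 0.3 passed camera in both fits, as did 1 of 100 unshifted lists in each. The simulated genes varied independently of each other. On the real arrays the estimated correlation of the interferon list was 0.758 without the block and 0.197 with it. This rate of false lists therefore does not carry over to lists of correlated genes.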

Results

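Gene expression was measured on 12 single-colour arrays of cells labelled as blood monocytes, from mice aged 6 to 8 weeks. The cells were sorted for CD11b, CD115 and high Ly6C, the phenotype of inflammatory monocytes, which leave the blood for inflamed tissue. By their labels, 6 arrays came from TRIM33 mice and 6 from WT mice. All 12 carry the LyzCre strain label, which names a recombinase driven from a lysozyme locus in myeloid cells, and whether the WT mice carry that recombinase is not given in the sources used here. The series title places the work in the resolution of colonic inflammation without TRIM33, a chromatin-binding cofactor of SMAD proteins. In each genotype 2 arrays are titled as mixes and 4 are not. The labels do not say that each array is a separate animal, so the p-values measure the spread between these arrays, which may be partly technical. The number of arrays limits the precision. Array medians lay between 4.16 and 4.25 on the log2 scale, and the highest correlation between 2 arrays was 0.992.

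The targeted gene followed the labels on every array. Trim33 fell by 0.79 on the log2 scale in the TRIM33 arrays (SE 0.067; limma, Benjamini-Hochberg adjusted p = 0.000637), from 6.92 ± 0.0794 (SD, n = 6) to 6.13 ± 0.0653 (SD, n = 6). All 6 TRIM33 arrays lay below all 6 WT arrays, the highest TRIM33 array at 6.23 and the lowest WT array at 6.81. The exact two-sided permutation test gave p = 0.00217, the smallest that 924 assignments allow, and 0.005 within the array sets described below, the smallest that 400 allow. Whether the probes of this feature lie inside the deleted part of the gene is not given in the sources used here, so the size of the fall does not measure how much transcript was left. The paralogs did not pass the test: Trim24 differed by -0.01 (SE 0.097), Trim28 by -0.07 (SE 0.246) and Trim66 by 0.03 (SE 0.133) on the log2 scale.

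The arrays fell into 2 sets of 6 that cut across genotype, each with 3 TRIM33 and 3 WT arrays. Xist, the RNA that silences an X chromosome in female cells, read 9.01 to 10.2 on the log2 scale on 6 arrays (the Xist set) and 3.36 to 3.64 on the other 6 (the Y set), while the Y-linked genes Eif2s3y and Kdm5d read 8.09 to 8.47 and 5.73 to 6.77 in the Y set against 2.19 to 2.89 and 2.47 to 3.27 in the Xist set. Cell cycle genes separated the sets too: the mean log2 value of the 19 measured members was 9.23 to 9.32 in the Xist set and 4.60 to 5.59 in the Y set. Ly6c2, which encodes the sorted antigen, read 12.2 to 12.5 in the Xist set and 12.3 to 12.5 in the Y set. Correlations between arrays were 0.986 to 0.992 within a set and 0.955 to 0.967 between sets, and the first principal component held 62.2% of the variance. All 4 mixes lay in the Y set. Because genotype is balanced over the sets, a fit with the set as a block has the same log2 folds and other standard errors. That fit was added after the data were seen, and its values stand beside those of the planned fit below.

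**Figure D1:**
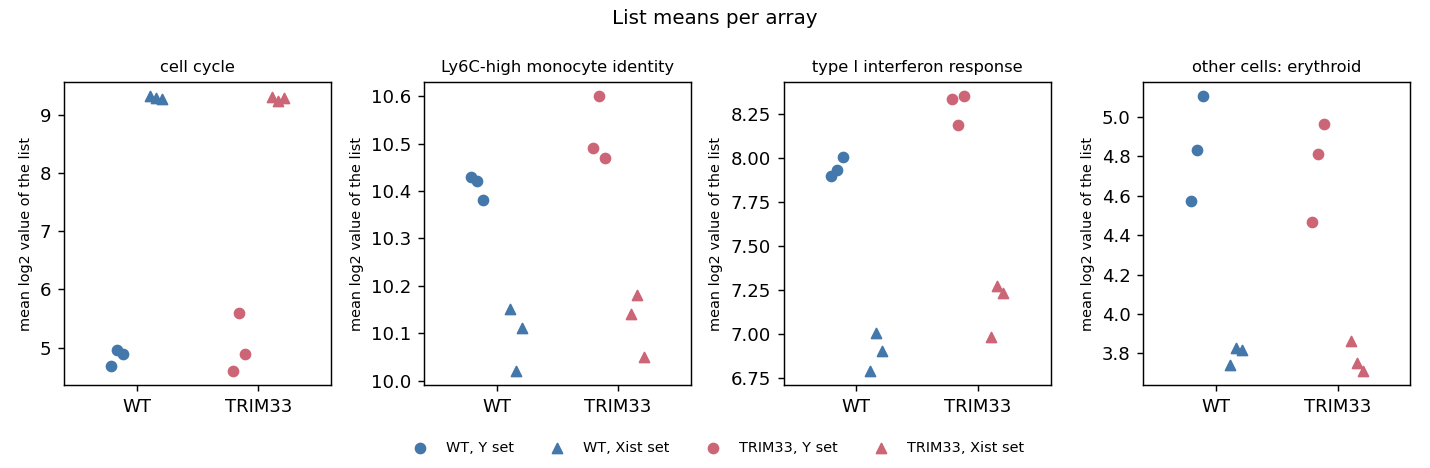
Mean log2 value of 4 gene lists on each array, by genotype on the horizontal axis, with circles for the Y set and triangles for the Xist set. The cell cycle list lies at 9.23 to 9.32 in the Xist set and at 4.60 to 5.59 in the Y set for both genotypes.

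The comparison of genotypes asks which transcripts differ in inflammatory monocytes when Trim33 is targeted. Few genes did. Besides the fall of Trim33, 4 genes rose: Apcdd1, which encodes a membrane inhibitor of Wnt signalling, by 2.99 on the log2 scale (SE 0.341, adjusted p = 0.00484), Stfa1, a stefin that inhibits cysteine proteases, by 2.74 (SE 0.251, adjusted p = 0.000653), Cep83, a centriole component, by 1.42 (SE 0.169, adjusted p = 0.00652), and the uncharacterised A930005H10Rik by 0.93 (SE 0.0872, adjusted p = 0.000653), all by limma with Benjamini-Hochberg adjustment and with 6 of 6 TRIM33 arrays above the WT mean. Apcdd1 went from 5.0 ± 0.247 to 8.00 ± 0.904 and Stfa1 from 3.18 ± 0.331 to 5.92 ± 0.596 (SD, n = 6). In all, 5 of 23279 genes passed, 4 higher and 1 lower, and 715 had an unadjusted p under 0.05. Chance would give such a p to a share of 0.05 of the genes, and 715 lies below that share. With a linear model without moderation Apcdd1 and Cep83 no longer passed (adjusted p = 0.0679 for both). For 46 genes, 0.198% of those tested, the 6 arrays of a genotype did not overlap those of the other. Exchangeable arrays would give 0.217%, or 50.4 genes, by chance. These arrays are not exchangeable, because a gene that parts the array sets cannot part the genotypes. The comparison therefore cannot decide whether 46 exceeds chance.

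With the array set as a block, 9 genes passed, 8 higher and 1 lower, among them all 5 of the planned fit. An unadjusted p under 0.05 was found for 1229 genes, close to the share of 0.05 that chance would give. The 4 further genes were Lyz1, a lysozyme gene, which rose by 3.56 on the log2 scale (SE 0.212; limma adjusted p = 1.25e-06 with the block and 0.114 without it), Oas1g, an oligoadenylate synthetase family member induced by interferon, by 1.70 (SE 0.174; 0.000341 and 1), Atp1b3, a sodium pump subunit, by 0.73 (SE 0.0756; 0.000341 and 0.114), and the histone gene H2bc18 by 1.77 (SE 0.227; 0.00383 and 1). Lyz1 went from 7.35 ± 1.25 to 10.9 ± 0.975 (SD, n = 6), and all 6 TRIM33 arrays lay above all 6 WT arrays. The exact permutation test gave p = 0.00217, as it does for each of the 46 genes without overlap. Lyz1 was picked for that test after its values were seen, so this p adds no support. Within the Y set alone, 3 arrays against 3, 8 genes passed, all higher: Apcdd1, Emp1, Lyz1, Stfa2l1, Cep83, Stfa1, Klra17 and Oas1g. Within the Xist set 3 did, all higher: Apcdd1, Lyz1 and H2bc18. Of the pair in both, Apcdd1 rose by 3.61 in the Y set and 2.38 in the Xist set, and Lyz1 by 3.38 and 3.74. In the 4 against 4 arrays not titled as mixes limma called 0 genes, with 565 at an unadjusted p under 0.05, and 9 genes with the array set as a block, 7 higher and 2 lower. Stfa1, Oas1g and H2bc18 belong to families of closely similar genes, whose probes may not tell the copies apart.

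**Figure D2:**
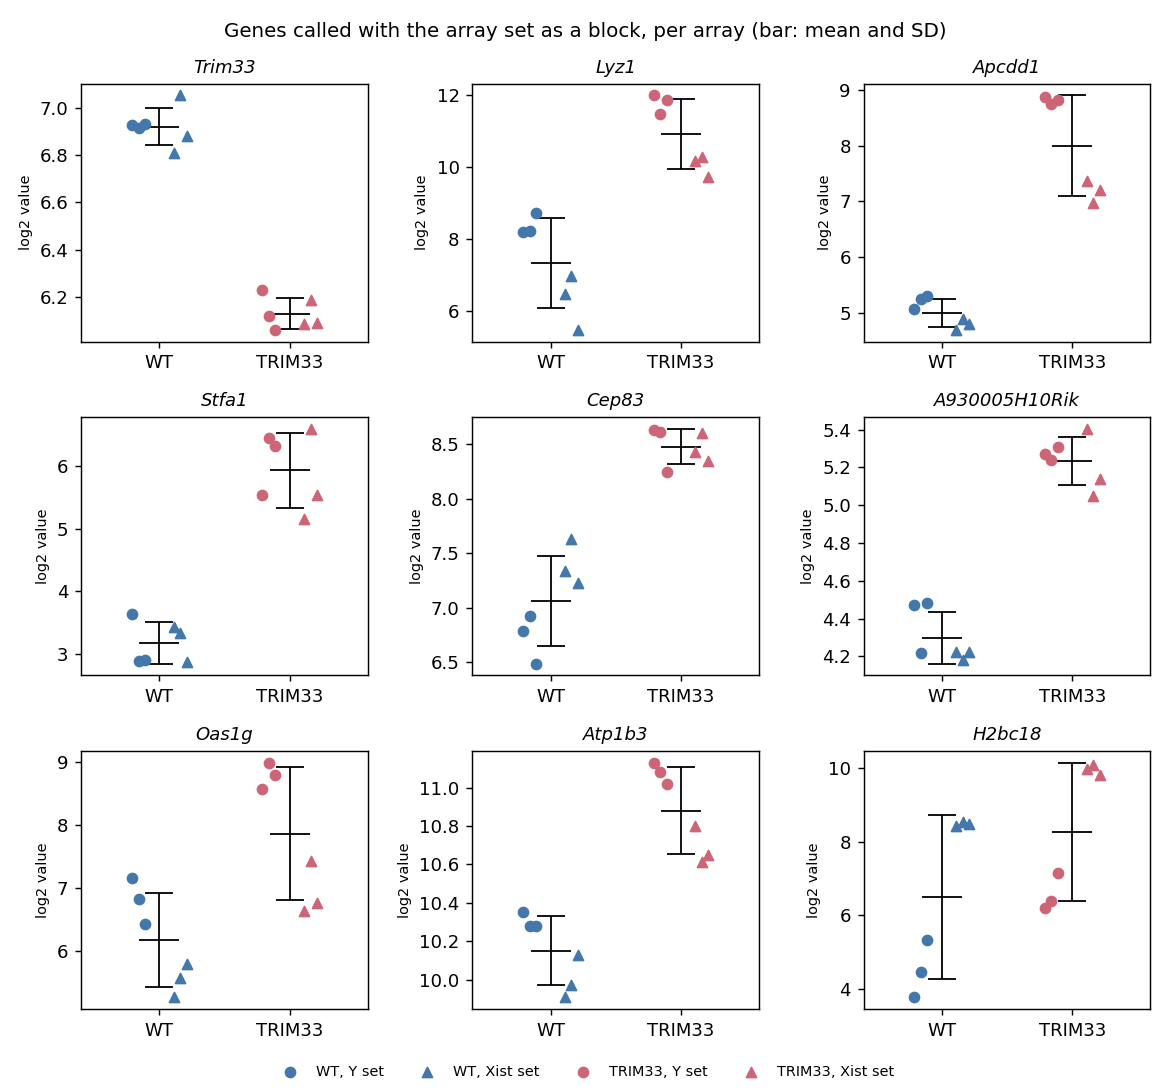
Log2 values on each array of the 9 genes past the threshold with the array set as a block, by genotype, with circles for the Y set and triangles for the Xist set; bars give the mean and SD of 6 arrays. Trim33 lies at 6.81 or above on the WT arrays and at 6.23 or below on the TRIM33 arrays.

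Only Trim33 passed among lower genes, so the next by p are given as values that did not pass. Capza1, an actin capping subunit, differed by -0.81 on the log2 scale (SE 0.166, limma adjusted p = 0.629), Vamp3, a vesicle fusion protein, by -0.43 (SE 0.0896), Dglucy by -0.61 (SE 0.155) and the histone gene H2bc21 by -0.69 (SE 0.176). Sox7, Zfp39, Nxf7, Efna4 and Erp27 lay between -0.39 and -0.31. Among higher genes that did not pass, the heme-binding protein gene Hebp1 differed by 2.11 (SE 0.416, adjusted p = 0.558), Klra17, a Ly49-type receptor, by 1.80 (SE 0.399), Gsg1 by 0.64 (SE 0.151), Zfp53 by 0.53 (SE 0.123) and Uqcr10, a respiratory chain subunit, by 0.36 (SE 0.0865).

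Genes of the type I interferon response were higher in the TRIM33 arrays as a list: all 28 measured members lay above 0, with a mean log2 fold of 0.30 (SE 0.061 with the array set as a block) and a median of 0.32. The list passed camera (Benjamini-Hochberg adjusted p = 7.3e-06), but not with the correlation between genes estimated from these arrays (adjusted p = 0.923 with an estimated correlation). With the array set as a block it passed camera (adjusted p = 3.21e-24), camera with an estimated correlation (adjusted p = 0.0302 with an estimated correlation) and fry, which tests whether the genes move one way on balance (adjusted p = 0.00855). The exact permutation test of the list mean gave p = 0.426 over all assignments and 0.010 within sets. Over all genes 0 members passed limma in either fit. Without the block 0 passed adjusted over the list alone and 0 had an unadjusted p under 0.05. With the block 17 passed adjusted over the list alone, and 20 had an unadjusted p under 0.05. Of members picked after their values were seen or by the naming rule, Oas2, an antiviral synthetase, differed by 0.74 on the log2 scale (SE 0.137), Isg15, a ubiquitin-like modifier, by 0.57 (SE 0.107), Usp18, which removes Isg15, by 0.43 (SE 0.0984) and Oas1a by 0.47 (SE 0.130), with the SEs of the blocked fit. The list mean differed by 0.34 in the Y set (camera adjusted p = 4.22e-18, and adjusted p = 0.201 with an estimated correlation) and 0.26 in the Xist set (1.62e-09, and adjusted p = 0.347 with an estimated correlation). The interferon gene Ifnb1 itself differed by 0.04 (SE 0.114), and the plasmacytoid dendritic cell list, which shares Bst2 with this list, by -0.02 (SE 0.064; camera adjusted p = 0.902), although its test ran upward.

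**Figure D3:**
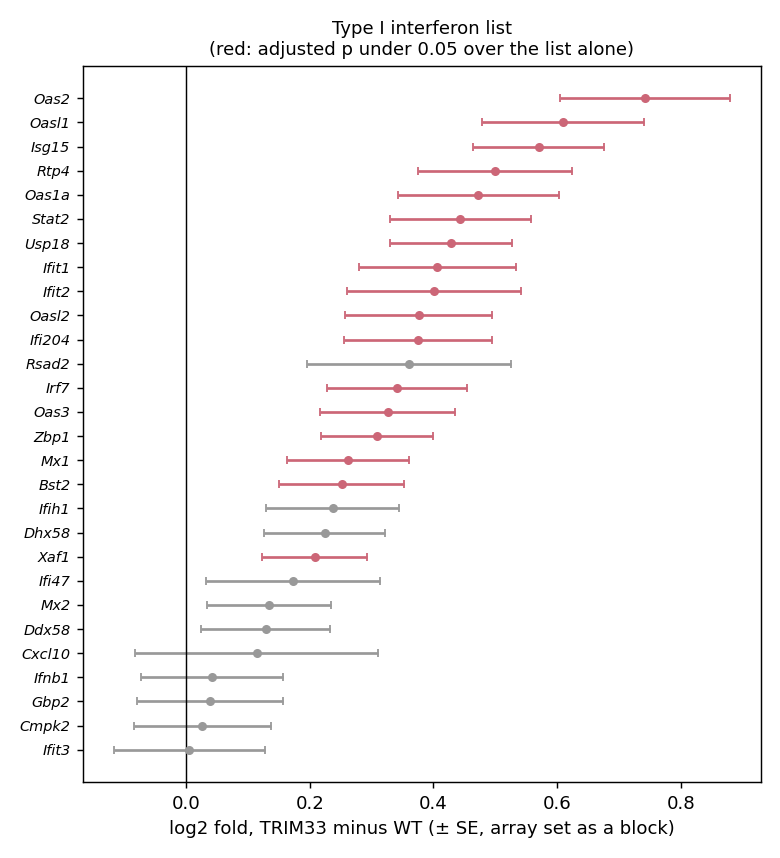
Log2 fold between TRIM33 and WT arrays of the 28 measured interferon genes, with standard errors from the fit with the array set as a block; red marks the 17 genes past the threshold adjusted over the list alone. Every gene lies above 0, with Oas2 at 0.74.

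Of the 27 lists, 5 passed camera in the planned fit and 8 with the array set as a block. Throughout, the SEs of list means are those of the fit with the array set as a block, which leaves out the spread between the sets. They do not belong to the planned p-values beside them. The planned fit holds that spread: the neutrophil list mean was 5.65 ± 1.06 in WT and 6.06 ± 0.927 in TRIM33 arrays (SD, n = 6). Respiratory chain genes were higher in 17 of 19 members, by a mean of 0.09 on the log2 scale (SE 0.0372; camera adjusted p = 0.00163, and adjusted p = 0.923 with an estimated correlation), with Sdhb at 0.34 (SE 0.120, without the block as for the genes below) and Ndufb5 at 0.20 (SE 0.0766). Their mean was 0.02 in the Y set (camera adjusted p = 0.593) and 0.16 in the Xist set (0.000183, and adjusted p = 0.347 with an estimated correlation). Neutrophil markers had a mean of 0.41 (SE 0.189; adjusted p = 0.00394, and adjusted p = 0.779 with an estimated correlation), 12 of 16 higher, with Stfa2l1 at 1.97 (SE 0.681) and Chil1 at 0.36 (SE 0.172). TRIM33 replicate 2 stood apart in the Y set, with a neutrophil list mean of 5.94 against 4.62 to 5.12 on the other 5 arrays and a cell cycle list mean of 5.59 against 4.60 to 4.96; without it the neutrophil shift with the block was 0.25 (camera adjusted p = 0.00244). Ribosomal protein genes had a mean of 0.08 (SE 0.0385; adjusted p = 0.0187, and adjusted p = 0.779 with an estimated correlation), 10 of 16 higher, with Rps14 at 0.40 (SE 0.105) and Rps24 at 0.42. The list of Trim33 and its paralogs had a mean of -0.21 (SE 0.0408; adjusted p = 0.0187, and adjusted p = 0.348 with an estimated correlation), of which Trim33 alone passed limma. With the block the adjusted p of these 4 lists was 0.000256, 3.1e-05, 0.0219 and 0.0222, and for each adjusted p = 0.154 with an estimated correlation. In the planned fit these lists no longer passed without some single array: the respiratory chain without TRIM33 replicate 4 or 5 or WT replicate 5, neutrophils without TRIM33 replicate 5 or WT replicate 5 or 6, ribosomal proteins without TRIM33 replicate 4 or 5 or WT replicate 5 or 6, and the paralogs without TRIM33 replicate 2 or WT replicate 5. With the block, ribosomal proteins no longer passed without TRIM33 replicate 5 or WT replicate 1, nor the paralogs without TRIM33 replicate 2 or WT replicate 5. The interferon list passed in every such fit, with and without the block.

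Lists for 3 further groups passed camera with the array set as a block but not in the planned fit, all lower. MHC class II and dendritic cell genes, which present antigen, were lower in 15 of 17 members, by a mean of -0.22 on the log2 scale (SE 0.129; camera adjusted p = 0.00314, and adjusted p = 0.259 with an estimated correlation; 0.169 without the block), with Xcr1 at -0.17 (SE 0.0738) and Zbtb46 at -0.16 (SE 0.107). In the Y set TRIM33 replicate 2 read lowest for this list, at 7.06 against 7.71 to 7.90 on the other 5 arrays, and for the Ly6C-low list, at 7.15 against 7.59 to 7.96. Without that array the MHC class II mean was -0.11 with the block and the list did not pass camera (adjusted p = 0.162). With all arrays it passed camera within each set (adjusted p = 0.0257 in the Y set and 0.0228 in the Xist set). With an estimated correlation it passed camera in neither set (adjusted p = 0.862 and 0.347). TGF-beta and SMAD pathway genes, the signalling that Trim33 is known to act in, were lower in 19 of 24 members, by -0.10 (SE 0.0276; adjusted p = 0.0363, and adjusted p = 0.154 with an estimated correlation; 0.154 without the block), with the inhibitory Smad7 at -0.44 (SE 0.184) and Ski at -0.32 (SE 0.173). Natural killer cell markers had a mean of -0.15 (SE 0.0598; adjusted p = 0.0295, and adjusted p = 0.154 with an estimated correlation; 0.0628 without the block), 11 of 13 lower, with Klre1 at -0.50 (SE 0.183) and Ncr1 at -0.18 (SE 0.0946). The exact permutation p of the list mean within sets was 0.010 for TGF-beta and SMAD genes, 0.065 for MHC class II genes and 0.05 for natural killer markers, and over all assignments 0.463, 0.595 and 0.0866. With the block, fry gave adjusted p = 0.0256, 0.272 and 0.123 for these lists. Adjusted over the list alone, the counts with the block were 1 gene for the respiratory chain, 1 for neutrophils, 2 for ribosomal proteins, 1 for Trim33 and its paralogs and 1 for eosinophils and basophils, and 0 for the MHC class II, TGF-beta and natural killer lists, where limma gave 0, 3 and 2 genes at an unadjusted p under 0.05. Without the block they were 1 gene for Trim33 and its paralogs and 1 for ribosomal proteins. The means in the Y and Xist sets were 0.60 and 0.23 for neutrophils, 0.10 and 0.06 for ribosomal proteins, -0.21 and -0.22 for Trim33 and its paralogs, -0.23 and -0.21 for MHC class II genes, -0.12 and -0.09 for TGF-beta and -0.12 and -0.18 for natural killer markers. With the block, the TGF-beta list no longer passed when any of 7 of the 12 arrays was left out, and the natural killer list when any of 5 was. The natural killer list also no longer passed with the block among genes with a mean above the median, where camera ran upward.

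**Figure D4:**
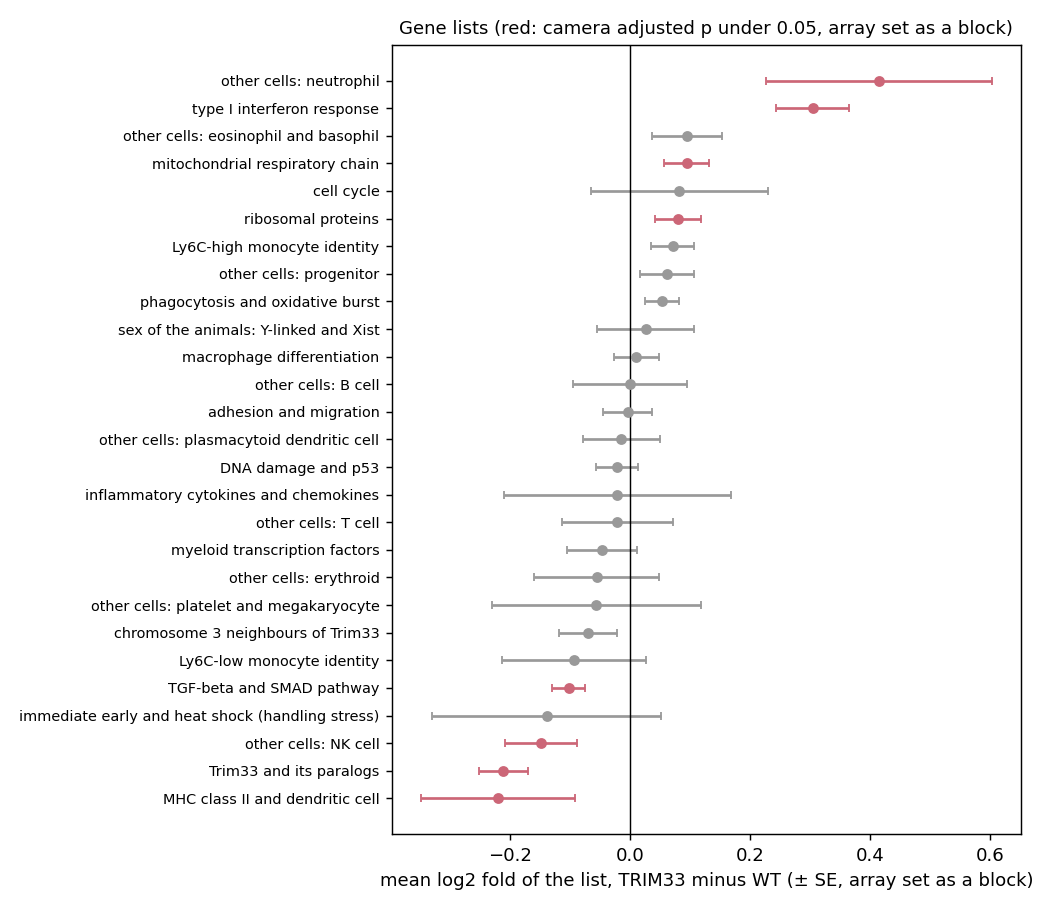
Mean log2 fold between TRIM33 and WT arrays of each of 27 gene lists, with standard errors from the fit with the array set as a block; red marks the 8 lists past camera in that fit. The neutrophil list lies highest at 0.41 and the MHC class II list lowest at -0.22.

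The remaining lists passed camera in neither fit. Markers of the sorted cells differed by a mean of 0.07 on the log2 scale for Ly6C-high monocytes (camera adjusted p = 0.121; Ly6c2 at 0.10, SE 0.0742, and Plac8 at 0.16, SE 0.117) and -0.09 for Ly6C-low monocytes (0.902; Cd300e at -0.29 and Cx3cr1 at -0.29). Macrophage differentiation genes had a mean of 0.01 and a median of -0.02 (Mertk at 0.32 and Gpnmb at 0.29), phagocytosis and oxidative burst genes 0.05 (Cyba at 0.14 and Fcgr1 at 0.35) and myeloid transcription factors -0.05 (Gata1 at 0.23 and Meis1 at -0.22). Inflammatory cytokines and chemokines had a mean of -0.02 (SE 0.189; Tnf at -0.50, SE 0.321, and Il6 at -0.12, SE 0.1). Adhesion and migration genes had a mean of -0.0045 against a median of 0.0030 and an upward test (Rac2 at -0.12 and S1pr5 at -0.33). Cell cycle genes differed by 0.08 (SE 0.147; Ccnb2 at 0.57 and Ccna2 at 0.35), DNA damage genes by -0.02 (Gadd45a at -0.25 and Phlda3 at 0.15) and handling stress genes by -0.14 (SE 0.191; Hsph1 at -0.48 and Atf3 at -0.31). In the Y set alone the handling stress list was lower and passed camera, at -0.31 (adjusted p = 0.0321, and adjusted p = 0.862 with an estimated correlation), against 0.03 in the Xist set (0.627), with Hsph1 at -1.16 and 0.19. The Y-set list difference leaned on WT replicate 4, which read 8.80. The other WT arrays of that set read 7.73 and 8.25, within the 7.69 to 8.32 of its TRIM33 arrays. WT replicate 4 and TRIM33 replicate 1, at 8.32, are the Y-set arrays not titled as mixes, and the mixes read 7.69 to 8.25. The neighbours of Trim33 on chromosome 3 differed by -0.07 (SE 0.0482, adjusted p = 0.271), with Tspan2 at -0.20 and Magi3 at -0.24.

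Markers of blood cells other than neutrophils and natural killer cells did not pass camera in either fit. The mean log2 fold was -0.00039 for B cells (Ms4a1 at -0.24 and Pax5 at -0.09), -0.02 for T cells (Cd4 at 0.20 and Thy1 at -0.26), -0.06 for erythroid cells (Kel at -0.21 and Epb42 at -0.10) and -0.06 for platelets (Itgb3 at -0.30 and Gp5 at -0.31). It was 0.09 for eosinophils and basophils (Prg2 at 1.11, SE 0.794, and Epx at -0.12) and 0.06 for progenitors (Hlf at 0.18 and Egfl7 at 0.21). For B and T cells the test ran upward against a mean and median below 0. The list of Y-linked genes and Xist differed by 0.03 (Kdm5d at -0.05 and Xist at 0.09), since both sets hold the genotypes in equal number. In the plasmacytoid list Spib differed by -0.37 (SE 0.340) and Bst2 by 0.25 (SE 0.176).

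The titles give a further factor, mixes against arrays not so titled. The genotype effect differed between them for 0 genes by limma's interaction test, with 527 at an unadjusted p under 0.05, and for 0 of 27 lists by camera (lowest adjusted p = 0.271, neutrophil markers). All mixes lie in the Y set and 3 of the 4 other arrays of each genotype in the Xist set, so the test was run again with the array set as a block, after the data were seen. It gave 0 genes by limma, with 865 at an unadjusted p under 0.05, and 5 lists by camera. The block removes the difference in level between the sets, but not a genotype effect that differs between them. For these 5 lists a difference between mixes and other arrays therefore stays partly confounded with one between the sets. The neutrophil shift, for example, was 0.60 in the Y set and 0.23 in the Xist set. The genotype difference was higher in the mixes for neutrophil markers by 0.71 (camera adjusted p = 0.000159), cell cycle genes by 0.35 (0.00121) and platelet markers by 0.31 (0.0364), and lower for MHC class II genes, at -0.33 (0.0132), and Ly6C-low markers, at -0.29 (0.0145). For each, adjusted p = 0.693 with an estimated correlation. Without TRIM33 replicate 2, a mix, the neutrophil, cell cycle, MHC class II and Ly6C-low lists did not pass camera (adjusted p = 0.373, 0.984, 0.984 and 0.936), nor did the MHC class II and Ly6C-low lists without TRIM33 replicate 1 or WT replicate 4 or 6. Platelet markers did not pass without TRIM33 replicate 1, 3 or 6 or any single WT array from replicates 2 to 5. In the mixes alone, 2 arrays against 2, 7 genes passed limma, all higher: Emp1, Apcdd1, Stfa1, Stfa2l1, Lyz1, Hebp1 and Oas1g. Trim33 differed by -0.83 on the log2 scale in the mixes and by -0.77 in the others, with limma adjusted p = 0.937 and 0.155 in those smaller fits. Between the array sets the genotype effect differed for 0 of 27 lists by camera (lowest adjusted p = 0.107, handling stress and respiratory chain genes) and for 1 gene. Stfa2l1, a stefin family member and neutrophil marker, differed by 3.65 between TRIM33 and WT arrays in the Y set (SE 0.284) and by 0.30 in the Xist set (SE 0.190), a difference of -3.35 (SE 0.371; limma interaction, adjusted p = 0.0116). Leaving out WT replicate 2, 3 or 6, or TRIM33 replicate 4 or 6, brought the count to 0, and leaving out TRIM33 replicate 3 brought it to 2.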

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

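All tests of explanations in this part were chosen after the results they bear on were seen, except the counts over other splits of the arrays, and of these the count of lists without the block over balanced splits was chosen after too.

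An array far from the others of its genotype was found in 8 of 210 groups of 6 examined, where chance gives 10.5. WT replicate 4 read highest for Tnf at 9.34, Atf3 at 10.9, Gsg1 at 3.99 and the cytokine and chemokine list at 6.50. TRIM33 replicate 1, the other Y-set array not titled as a mix, read 6.28 for that list, against 5.48 to 5.84 on the mixes. Whether the list follows preparation was not tested apart from genotype. WT replicate 5 read highest for Efna4 at 4.16. TRIM33 replicate 5 read highest for Chil1 at 3.92, and TRIM33 replicate 3 for Ms4a1 at 3.43 and the B cell list at 4.71. Stfa2l1 was picked out because its genotype effect differed between the array sets, by -3.35 on the log2 scale (Xist set minus Y set). Over 100 splits within sets, 12 gave at least the 1 gene of the real split, with a highest other count of 2, so chance cannot be excluded there.

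For the counts of changed genes, chance groupings of the arrays fell short. Of 100 splits of the 12 arrays, 1, the real one, gave as many as its 5 genes, and the highest other count was 1. Of 100 splits that kept 3 arrays of each set on each side, 1, the real one, gave as many as its 9 genes, and the highest other count was 1. With arrays as the units, a chance assignment of these arrays can be excluded for both counts. The labels do not say that each array is a separate animal, so the splits cannot exclude chance differences between animals. Both counts include Trim33, the targeted gene. Over all splits it cannot be excluded for the count of lists without the block: 56 of 100 gave at least the 5 lists of the real split, with a highest other count of 22, which points to a structure of the samples, since splits unbalanced over the array sets gave the high counts. Over 100 splits with 3 arrays of each set on each side, like the real one, 2 gave at least 5 lists without the block, with a highest other count of 6. A count this high was rare among such splits, but another split exceeded it. The scheme was also chosen late, and the 5 include the list of Trim33 and its paralogs, which holds the targeted gene. Chance is therefore not taken as excluded for this count. With the block chance cannot be excluded either: 13 of those 100 splits gave at least 8 lists, with a highest other count of 10. Within each set 10 splits are too few for a share under 0.05; the real counts were 8 genes in the Y set and 3 in the Xist set, and the highest others 1 and 0.

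The interferon list was higher in TRIM33 arrays, with a mean log2 fold of 0.30. Plasmacytoid dendritic cells in the sort would bring their own markers, but the mean of 8 such markers without Bst2 differed by -0.049 (SE 0.0666), which argues against them. No single array carried it: the lowest mean with an array left out was 0.28 (SE 0.0644). Of the 20 members with an unadjusted p under 0.05 with the block, 1, or 5% of them, lay near Trim33 or Lyz1. Near means among the 250 nearest measured genes on either side, where 4.16% of all measured genes lay. Most of these members therefore do not lie in DNA around either locus. The test cannot decide whether DNA carried along acts on genes elsewhere. The genotype and any difference in housing or handling between the groups stay open. So does the recombinase, because whether the WT mice carry it is not given in the sources used here. A rise with Trim33 loss is therefore a hypothesis that may hold, and it rests on the blocked fit.

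Genes with small p lay near one another on the chromosomes. Of 55 placed genes with an unadjusted p under 0.001 with the block, 10 lay within 5 measured genes of another, against a mean of 1.28 in 10000 random sets (permutation p = 0.0003), which argues against chance spacing; they were Emp1, Gsg1 and Hebp1, Lyz1 and Yeats4, Stfa1, Stfa2l1 and Stfa3, and H2bc18 and H2bc21. Copies that share probes are argued against for the 5 of the 10 with no family member beside them and for the histone genes, which moved in opposite directions (H2bc21 -0.69, SE 0.152, against H2bc18 1.77), while the stefin genes, all higher (lowest Stfa3 at 0.75, SE 0.162), could still share probes. Whether DNA carried along acts on genes elsewhere was not tested. DNA carried along around Trim33 or the lysozyme genes cannot hold all 10 genes, since 6 of them lie on other chromosomes than Trim33 and Lyz1. For genes near those loci it cannot be told apart from a regional effect of Trim33 loss: among uncalled genes all 12 combinations of window and p limit looked at held more than the chance number, but 3 of them with a hypergeometric p under 0.05 (p from 0.0098 to 0.491), and none of the 12 is preferred.

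The 2 sets of arrays differ by far more than genotype does: for 423 genes all arrays of one set lay over 1 log2 unit above all arrays of the other, 337 higher in the Xist set and 86 in the Y set. That 17 of them, or 4.03% of those placed, lie on the X or Y chromosome argues against sex of the animals alone. Red cells and platelets in the Y set alone are also argued against, because the cell cycle list lay 4.40 higher in the Xist set by median, while the Ly6C-high list differed by -0.33. Dividing precursors in the Xist set could account for the 19 of 19 cell cycle genes that were higher on every one of its arrays. Of 11 progenitor genes 3 were higher so, while 2, Flt3 among them, were higher on every Y-set array, so the test stays undecided. Mpo, Elane and Myb, which are not on the progenitor list, were also higher on every Xist-set array, as given below. They were picked after their values were seen. Batch and any difference in tissue or sort between the sets were not recorded in the labels and stay untested.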

How the results depend on the processing

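The array set fits, as a block or within a set, were chosen after seeing the data; the other alternatives were planned. Signal over background limits dim genes most.

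The planned count of 5 genes went to 42 with an unadjusted p and a fold of at least 1.5, to 3 with a linear model without moderation, to 0 in arrays not labelled mix, to 9 with the array set as a block, to 8 in the Y set and to 3 in the Xist set. The arrays not labelled mix gave 9 genes with the block, so their number alone did not bring the count to 0. Leaving out each array gave 5 to 9, the 9 without TRIM33 replicate 4. The blocked count of 9 went to 60 with an unadjusted p and fold; leaving out each array gave 9 to 15, the 15 without TRIM33 replicate 4.

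Trim33 kept its fall in every alternative. Its log2 fold was -0.77 in arrays not labelled mix, -0.83 in the mixes with or without the block, -0.79 in the Y set and -0.79 in the Xist set, each no longer past the threshold (limma adjusted p 0.155, 0.937, 0.134 and 0.227); with the block it passed in arrays not labelled mix (adjusted p = 0.0457). Leaving out each array gave -0.81 to -0.76 in both fits.

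The planned count of 5 lists went to 0 with an estimated correlation, 1 with fry directional, 1 with fry mixed, 3 with quantile normalization again, 2 in arrays not labelled mix and 8 with the block. Leaving out each array gave 1 (without WT replicate 5) to 11 (without TRIM33 replicate 1). The blocked count of 8 went to 1 with an estimated correlation, 3 with fry directional, 4 with fry mixed and 3 in arrays not labelled mix; leaving out each array gave 4 (without TRIM33 replicate 2) to 11 (without TRIM33 replicate 1). The cause was not tested. The natural killer mean with the block shrank from -0.15 to -0.0068 among genes with a mean above the median, where camera ran upward and did not pass (adjusted p = 0.964).

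The genotype effect differed between mixes and other arrays for 0 to 1 genes when each array was left out, 0 to 2 with the array set as a block (2 without TRIM33 replicate 3), and between the array sets for 0 to 2; the latter was 0 among genes with a mean above the median, a filter at 4.21 that removes Stfa2l1, at 3.83.

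The mix number as a replicate block gave 6 genes against 5, and 9 with the array set as a block. The numbers share 2 pairs, with correlations of deviations of 0.138 and 0.217 for the same number and 0.0648 and -0.027 for crossed ones, so they were not taken as a pairing. The block changed no count by over 1.5 times.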

Other observations

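The tests in this part were chosen after the results were seen. Beyond the cell cycle, the array sets differed in granule and blood cell genes, given here as values chosen after they were seen and not as a comparison of groups. Mpo and Elane, granule enzymes made in myeloid precursors, read 10.9 to 11.6 and 10.3 to 10.8 on the log2 scale in the Xist set against 4.74 to 5.15 and 3.82 to 5.56 in the Y set. Myb, a transcription factor of immature cells, read 7.79 to 8.10 against 3.52 to 4.12, while Kit read 3.57 to 4.16 against 3.28 to 3.66. The haemoglobin gene Hbb-b1 read 11.1 to 11.4 in the Y set and 2.76 to 4.31 in the Xist set. Ace and Treml4, markers of Ly6C-low monocytes, read 8.25 to 9.58 and 8.68 to 9.85 in the Y set against 4.73 to 5.61 and 5.75 to 6.76. The mean of the interferon list was 7.90 to 8.35 in the Y set and 6.79 to 7.27 in the Xist set, a gap wider than the genotype shift within either set.

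Lyz1 had the largest rise among the genes called with the block. The LyzCre strain label, which names a recombinase at a lysozyme locus, is carried by the WT and the TRIM33 arrays alike, so the labels do not tie the Lyz1 difference to it; Lyz2 is not analysed here. Of the 5 nearest measured genes on each side of Lyz1, Yeats4 had the smallest p in the blocked fit (log2 fold 0.36, SE 0.0863, not past the threshold), and Cpm differed by -0.18 and Mdm2 by -0.07.

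Around both loci, without Trim33 and Lyz1 themselves, all 12 combinations of window and p limit held more small-p genes than the chance number when called genes were counted too, 11 of them with a hypergeometric p under 0.05 (p from 0.000416 to 0.169). Of the 7 genes called with the block other than Trim33 and Lyz1, 3 lay among the 250 nearest measured genes on either side: A930005H10Rik and H2bc18 on the chromosome of Trim33 (log2 folds 0.93 and 1.77) and Cep83 on that of Lyz1 (1.42). Capza1 and Frrs1, not called, lay on the chromosome of Trim33 with -0.81 and -0.56.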
